A study of Mus musculus with 4 samples.

How the data were processed

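RNA was measured by paired-end sequencing in 4 samples of mouse macrophages derived from MCA fibrosarcoma tumours and treated in culture with exosomes, which are small vesicles released by cells. The treatment labels divide the samples into 2 that received exosomes high in MEK1 and 2 that received exosomes low in MEK1, the latter also marked GFP. MEK1 is the kinase encoded by Map2k1 that phosphorylates the ERK kinases. Per the labels' protocols, RNA was taken up in TRIzol, libraries were made from 750 ng of RNA with a stranded mRNA kit, and about 25000000 reads of 100 bp were aimed at per sample. The labels do not say whether the samples of a group came from separate cultures or animals. The authors' p-values rest on the model of their test program, whose settings are not given. They speak at most for variation between these samples, which may be technical.

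The submitters' processing notes name FastQC 0.73, TopHat, Cufflinks, Cuffdiff and the mouse build mm10, without settings. The values used here are from a single table of the authors' comparison, laid out as Cuffdiff writes its gene test per the file headers. It holds 1 FPKM value per group as the authors deposited it (fragments per kilobase of transcript, scaled to the size of the library), together with the authors' deposited test score, p-value and q-value. The table does not state which samples entered each group value, and the library normalization setting is not given in the sources used here. Values per sample were not used here. Because of this no SD between samples is printed, no spread between samples could be computed, and every test of a single gene is the authors' own. The depth of each sample is unknown, since FPKM keeps no counts.

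The table names its columns MEK1 exo and GFP exo, and the latter was matched to the MEK1-low group through the treatment label, which carries the word GFP. Fold changes were computed as the MEK1-hi value over the MEK1-low value. The deposited log2 fold change column was not used, because a spreadsheet error text stood in 1555 of its cells. Over tested loci above 0 in both groups, the computed log2 values differed from the deposited ones by at most 0.000212. The deposited q-value equalled a Benjamini-Hochberg adjustment of the deposited p-value over the tested loci within 5.19e-07. Of 55082 gene identifiers in the table, 54824 (99.5%) were matched to a symbol, and gene positions were taken from GENCODE M21, which uses the same build. Start positions in the table count from 0 and are printed counting from 1.

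A row of the table is a locus, which can join several overlapping genes. Such joined loci made up 863 of the 12648 loci tested, and reads of their genes cannot be told apart here. Genes with near-identical copies elsewhere in the genome share reads with those copies, so their levels are uncertain.

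A gene was called where Cuffdiff had tested it and the deposited q-value was under 0.05. Choices made before the data were examined comprised this threshold, 33 gene lists from textbook knowledge, the alternatives of processing and a rule for the genes named. The rule took Map2k1, Map2k2, Mapk3 and a further gene in any case. It took the 12 largest rises and the 12 largest falls among called genes with a single symbol, at least 1 FPKM in the higher group and above 0 in both. It also took up to 4 called members of each list, by absolute log2 fold change, and up to 2 members of the highest mean from a list with no called member. Called genes listed at 0 in a group would have been named too, but there were 0 of them. Some further list members are named beside the counts of their list and, like the genes said to be so in the closing section, were chosen after their values were seen. Some genes that the rule took are not reported or drawn here, though list counts and medians include them. Cox4i1 and Mvd were members of the fixed lists and are not analysed here.

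For each list, the median log2 fold change was taken over its loci tested at 1 FPKM or more in either group, on the log2(FPKM + 1) scale, which understates the change of low genes. It was compared with the medians of 10000 random lists of the same size, matched on mean expression in 20 bins and drawn with a fixed seed from the 11804 loci tested at that level. A list is described as outside the random range where its median fell below the 2.5th or above the 97.5th percentile. Whether a list result held under an alternative was judged by this side of the range alone, a rule simplified after a first run. This percentile describes these group values and is not a p-value for the treatment. The count of called members is given over all loci tested and, from the deposited p-values, adjusted over the list alone. On simulated data, 4.5% of 200 lists of 18 loci without a shift fell outside the range, and 100% did so with a shift of -0.25, for loci simulated as independent. Lists of other sizes were not simulated, and short lists had wider ranges. That of the 3 neutrophil loci ran from -0.34 to 0.21, so a shift of -0.25 could lie inside it. Genes of a pathway that vary together between samples would fall outside more often by chance.

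Alternatives comprised other q thresholds, minimum levels, a minimum fold change, a recomputed adjustment, centring on the median, pseudocounts of 0.1 and 5 FPKM, means in place of medians and lists without their most changed member. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.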

Results

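Transcripts were measured in macrophages derived from MCA fibrosarcoma tumours of mice, after treatment in culture with MEK1-hi exosomes (2 samples) or MEK1-low exosomes (2 samples). The comparison addresses how macrophage transcripts differ with the MEK1 content of the exosomes they received. The labels also mark the MEK1-low exosomes as GFP, so an effect of MEK1 content cannot be told apart from one of that difference. No untreated macrophages were among the 4 samples, so each rise or fall below is relative to MEK1-low exosomes. All levels below are the authors' group values in FPKM, 1 per group, so no spread between samples accompanies them. The table held 53139 loci, of which the authors' Cuffdiff test had covered 12648. The depth of each sample is unknown. Both groups showed similar numbers of loci at 1 FPKM or more, 11575 with MEK1-low and 11567 with MEK1-hi exosomes. The 10 loci with the highest values took 18.1% of the FPKM total with MEK1-low exosomes and 17.6% with MEK1-hi exosomes.

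Macrophage transcripts were abundant in both groups. Lyz2, the lysozyme of myeloid cells, stood at 12303 FPKM with MEK1-low and 13148 FPKM with MEK1-hi exosomes. Of the 17 macrophage identity genes tested, Cd14, the lipopolysaccharide co-receptor, fell from 213 to 136 FPKM (q = 0.00349 in the authors' deposited table), and the other 16 did not pass. Adjusted over the list alone, the count was the same, with 1 lower. The median log2 fold change of this list was -0.13, at percentile 3.98 of random lists.

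Map2k1 itself, at chromosome 9 from 64185770 to 64253631 (mm10), did not pass the test in the recipient cells. Transcript levels do not measure MEK1 protein, including any brought by the exosomes. The Map2k1 level was 63.3 FPKM with MEK1-low and 57.0 FPKM with MEK1-hi exosomes, a log2 fold change of -0.15 (p = 0.341, q = 0.999 in the authors' deposited table). Map2k2, which encodes MEK2, stood at 92.8 and 94.6 FPKM (q = 0.999 in the authors' deposited table). Mapk3, which encodes ERK1, stood at 164 and 137 FPKM and did not pass the test either (q = 0.711 in the authors' deposited table). None of the 15 MEK1-ERK pathway components was called by Cuffdiff, also adjusted over the list alone, and 1 was lower at an unadjusted p under 0.05 in the authors' deposited table. Their median log2 fold change was 0.02 and their mean was -0.01.

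In the authors' deposited table, 309 loci passed the threshold, 95 higher and 214 lower with MEK1-hi exosomes, so that 69.3% of them were lower. These were 2.44% of the loci tested. A change of at least 2-fold was reached by 29 of the higher and 85 of the lower loci. The smallest absolute log2 fold change among called loci was 0.48, and the median was 0.85 among the higher and -0.87 among the lower ones. The smallest p in the authors' deposited table, 5e-05, was shared by 181 loci (q = 0.00349), so p-values do not rank those loci. The median log2 fold change of all loci at 1 FPKM or more was 0.00, with an SD of 0.40 across loci.

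Ccl7 and Ccl2, neighbouring genes for chemokines that attract monocytes, had the largest rises among called genes with a single symbol and at least 1 FPKM. Ccl7 (chromosome 11, 82045712 to 82047525) rose 15.0-fold, from 5.01 to 75.1 FPKM, and Ccl2 (chromosome 11, 82035571 to 82037453) rose 5.27-fold, from 9.10 to 47.9 FPKM. Slco2b1, an organic anion transporter, rose from 1.27 to 6.004 FPKM, and the sodium-proton exchanger gene Slc9a9 from 2.43 to 7.77 FPKM. Mmp27, of the matrix metalloproteinase family, rose from 1.67 to 6.31 FPKM, and the kinase gene Dmpk from 1.36 to 4.87 FPKM. Folr2, a folate receptor of tissue macrophages, rose from 34.5 to 88.7 FPKM, and Ccl6 from 24.3 to 63.9 FPKM. Tpbgl, Nanos1, Fam117a and Epas1, the last a hypoxia-inducible transcription factor, also rose, to between 1.42 and 2.54 FPKM. The calls of Fam117a and Epas1 ended where an absolute test statistic of at least 2 was required, theirs being 1.77 and 1.93 in the authors' deposited table. The q-values of these 12 genes in the authors' deposited table lay between 0.00349 and 0.0181.

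The largest falls were led by Cxcl13, a chemokine that attracts B cells (chromosome 5, 95956951 to 95961068), which was 8.11-fold lower, at 11.5 FPKM with MEK1-low and 1.41 FPKM with MEK1-hi exosomes. Ly6i, of the Ly6 family of surface proteins, fell from 188 to 25.6 FPKM, and Hp, which encodes haptoglobin, from 180 to 25.8 FPKM. Fpr1, a receptor for formylated peptides, fell from 40.8 to 9.22 FPKM. Clec4e, which encodes the pattern-recognition receptor Mincle, fell from 28.4 to 6.91 FPKM. Slc13a3, a dicarboxylate transporter, fell from 35.3 to 8.98 FPKM, and Pcx, which encodes pyruvate carboxylase, from 4.37 to 1.15 FPKM. Pla2g2d and Tmem178 fell from 2.76 to 0.536 FPKM and from 3.10 to 0.695 FPKM. Susd2, Aif1l and Cpeb1 fell too, from levels of 1.32, 2.15 and 1.40 FPKM. Aif1l and Cpeb1, with test statistics of -0.923 and -1.13 in the authors' deposited table, were no longer called at an absolute statistic of at least 2. The q-values of these 12 genes in the authors' deposited table lay between 0.00349 and 0.0157.

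**Figure D1:**
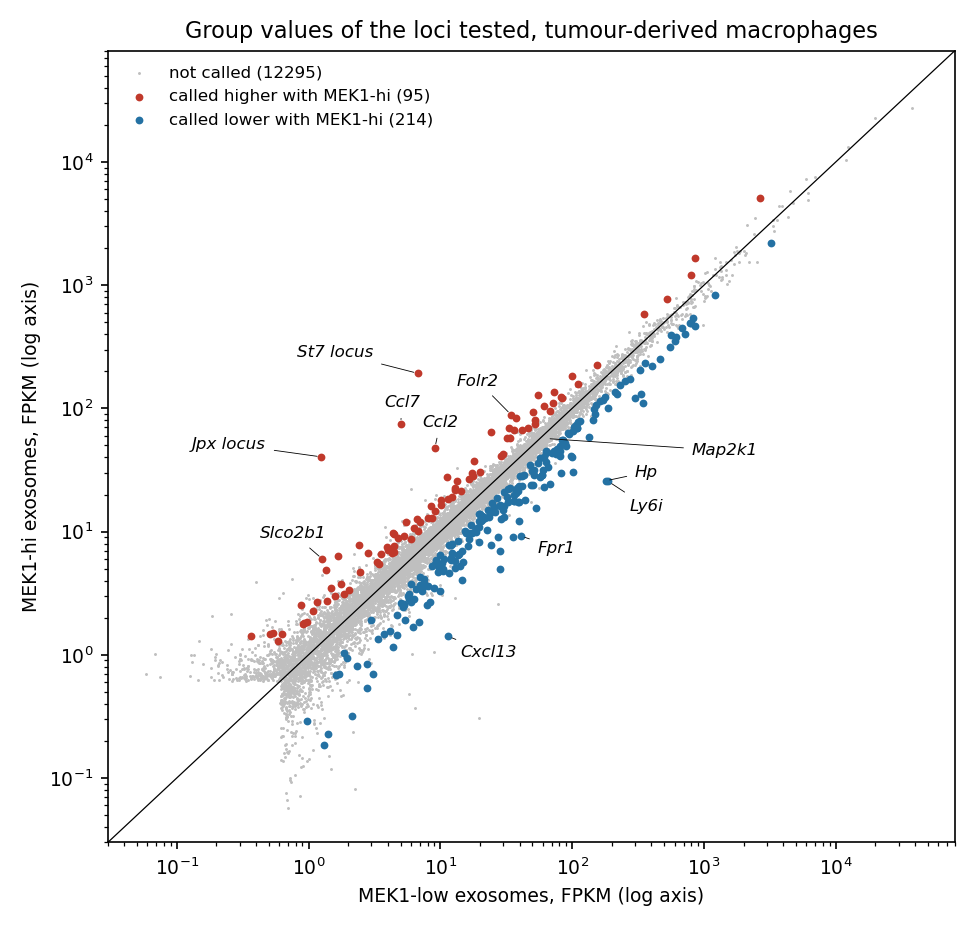
Group FPKM of tested loci with MEK1-low exosomes (x axis, log scale) and MEK1-hi exosomes (y axis, log scale), 1 point per locus, red where called higher, blue where called lower and grey where not called; the line marks equal values. The 95 red and 214 blue points lie off the line, with Ccl7 at 5.01 and 75.1 FPKM and Ly6i at 188 and 25.6 FPKM; 42 tested loci listed at 0 in a group and 2 loci under 0.03 FPKM in a group are not drawn.

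Chemokine genes went both ways. In the authors' deposited table, 3 of the 21 tested rose (Ccl2, Ccl6 and Ccl7) and 5 fell. The 5 that fell were Cxcl1, from 9.89 to 3.29 FPKM, Cxcl2, from 43.9 to 18.1 FPKM, Cxcl3, from 134 to 58.7 FPKM, and Cxcl5, from 4.67 to 2.10 FPKM, which all attract neutrophils, and Ccl5, from 49.3 to 31.1 FPKM. Adjusted over the list alone, 3 rose and 7 fell. The interferon-induced chemokines Cxcl9 (2.47 and 1.10 FPKM) and Cxcl10 (2.84 and 1.11 FPKM) did not pass over all loci tested, with q-values of 0.606 and 0.116 in the authors' deposited table. The median log2 fold change of the list was -0.00, at percentile 53.6 of random lists, while its mean was 0.11, at percentile 98.0 of random means.

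NF-kB target genes had lower values in 18 of 20 members. In the authors' deposited table, 10 of the 20 tested fell and 0 rose. Adjusted over the list alone, 13 fell and 0 rose, with 0 higher at an unadjusted p under 0.05. Traf1, a signalling adaptor, fell from 7.87 to 2.53 FPKM, Sod2, the mitochondrial superoxide dismutase, from 333 to 132 FPKM, and Nfkbie, an inhibitor of NF-kB, from 28.7 to 12.7 FPKM. The NF-kB subunit genes Relb and Nfkb2 fell from 30.6 to 16.2 FPKM and from 37.8 to 20.7 FPKM. Tnfaip3, an inhibitor of NF-kB signalling, stood at 51.4 and 49.4 FPKM (q = 0.999 in the authors' deposited table). The median log2 fold change was -0.60, below all 10000 random lists, whose middle 95% ran from -0.10 to 0.08.

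Pro-inflammatory markers of the M1 type also fell, 5 of 15 tested in the authors' deposited table with 0 higher, and 8 lower and 1 higher adjusted over the list alone. The formyl peptide receptor locus of Fpr2 and Fpr3, whose reads are joined, fell from 28.3 to 4.97 FPKM. Il1b, which encodes interleukin 1 beta, fell from 6.19 to 1.69 FPKM, Acod1, the enzyme that makes itaconate, from 52.8 to 15.4 FPKM, the scavenger receptor gene Marco from 61.7 to 23.2 FPKM, and Tnf from 90.6 to 49.8 FPKM. Nos2, Il6, Il12a and Il12b stood under 0.1 FPKM in both groups and were not tested. The median of these M1-type markers was -0.65, below all random lists. Of 17 markers of alternative activation (M2 type) tested, the mannose receptor gene Mrc1 rose from 17.5 to 29.9 FPKM and F13a1 from 0.900 to 1.79 FPKM, and 0 fell in the authors' deposited table. Adjusted over the list alone, 4 rose and 0 fell. Values were higher in 9 and lower in 8 of the 17, and at an unadjusted p under 0.05, 5 were higher and 3 lower. Among the lower, Mgl2 stood at 1.09 and 0.298 FPKM and Chil3 at 1.74 and 0.518 FPKM, neither of them called. Arg1, which encodes arginase, stood at 87.7 and 121 FPKM (q = 0.0749 in the authors' deposited table). The median of these markers was 0.00, at percentile 56.1, and 0.18, at percentile 99.6, over members of at least 5 FPKM, which leaves out Mgl2 and Chil3.

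Genes of the sterol biosynthesis list were lower throughout. All 19 tested had lower values with MEK1-hi exosomes, 9 of them fell in the authors' deposited table, and 13 fell adjusted over the list alone, with 0 higher at an unadjusted p under 0.05. Sc5d and Sqle, enzymes of the pathway, fell from 10.5 to 4.92 FPKM and from 10.4 to 4.995 FPKM, and the sterol carrier gene Stard4 from 5.32 to 2.52 FPKM. Srebf2, which encodes the transcription factor SREBP2 that drives this pathway, fell from 32.8 to 17.4 FPKM in a locus joined with a predicted gene. The median log2 fold change was -0.66, below all random lists, whose middle 95% ran from -0.10 to 0.12.

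Genes of lipid handling and cholesterol efflux showed higher values in 14 of 18 members. In the authors' deposited table, the fatty acid transporter gene Cd36 rose from 859 to 1658 FPKM and the fatty acid binding protein gene Fabp4 from 52.5 to 80.8 FPKM. Nr1h3, which encodes the sterol sensor LXR alpha and shares its locus with Gm13783, fell from 63.1 to 43.7 FPKM. Adjusted over the list alone, 8 rose and 1 fell, beside 2 and 1 over all loci tested. Abcg1, a cholesterol exporter, stood at 33.6 and 60.7 FPKM (q = 0.103 in the authors' deposited table). The list's median was 0.30, above all random lists.

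**Figure D2:**
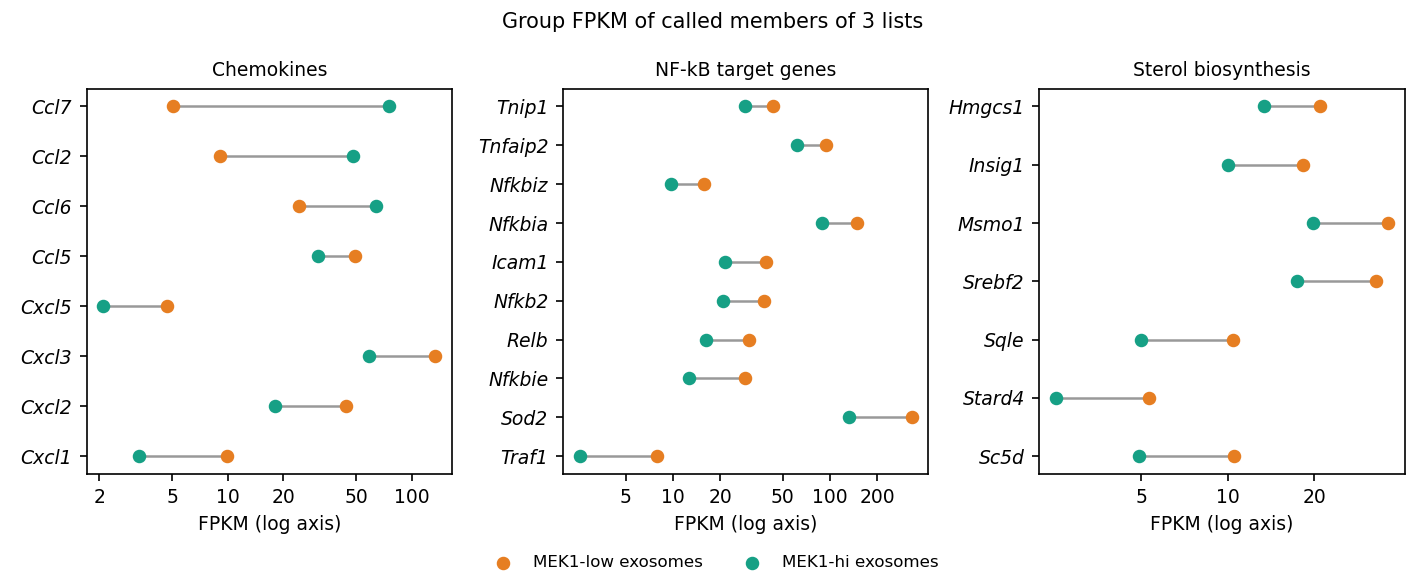
Group FPKM (x axis, log scale) with MEK1-low exosomes (orange) and MEK1-hi exosomes (green) for members of the chemokine, NF-kB target and sterol biosynthesis lists that the authors' test called; a line joins the group values of a gene. Only Ccl7, Ccl2 and Ccl6 lie higher with MEK1-hi exosomes among the 25 genes drawn, of 27 called.

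Genes of the NRF2 and oxidative stress response were lower in 16 of 17 members. Slc7a11, the cystine transporter, fell from 36.1 to 17.6 FPKM, the quinone reductase gene Nqo1 from 59.2 to 29.1 FPKM, and the thioredoxin gene Txn1 from 566 to 395 FPKM. These were the 3 that fell in the authors' deposited table, against 10 adjusted over the list alone, and 0 rose in either. Hmox1, which encodes heme oxygenase, stood at 1855 and 1828 FPKM (q = 0.999 in the authors' deposited table). The list's median was -0.40, below all random lists.

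Antigen presentation genes had lower values in 14 of 16 class I and 8 of 10 class II members. H2-Q7, a non-classical class I gene that shares near-identical sequence with its neighbours, fell from 100.0 to 40.2 FPKM. It was the 1 of 16 class I presentation genes called in the authors' deposited table, and 5 fell adjusted over the list alone. H2-K1 stood at 2507 and 1549.6 FPKM (q = 0.0681 in the authors' deposited table). The class I median was -0.21, at percentile 0.130. None of 10 class II presentation genes was called by Cuffdiff, also adjusted over the list alone, and 4 were lower at an unadjusted p under 0.05. Cd74, the invariant chain, stood at 3373 and 2772 FPKM, and the protease gene Ctss at 4375 and 3552 FPKM. The class II median was -0.30, at percentile 0.385.

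Of 13 loci of interferon-gamma and guanylate-binding genes, Gbp2 fell from 5.79 to 2.85 FPKM and 0 rose in the authors' deposited table. Adjusted over the list alone, 2 rose and 3 fell, with several of these genes joined in 1 locus. Their median was -0.33, at percentile 0.04. Of 36 type I interferon-stimulated genes, Ifi205 and Ifit1 fell, from 3.35 to 1.34 FPKM and from 17.1 to 11.3 FPKM, 0 rose, and the counts were the same adjusted over the list alone. Their median was -0.06, at percentile 6.46.

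Among 18 targets and feedback genes of ERK signalling tested, Ccnd1, which encodes cyclin D1, rose from 33.2 to 69.1 FPKM and the transcription factor gene Etv5 from 20.1 to 30.7 FPKM, and 0 fell over all loci tested. Adjusted over the list alone, from the authors' deposited p-values, 6 rose and 4 fell. The phosphatase gene Dusp6 stood at 73.6 and 101 FPKM (q = 0.198 in the authors' deposited table), and Fos at 211 and 157 FPKM (q = 0.221 in the authors' deposited table). The list had a median of 0.11, at percentile 98.3. Without Ccnd1, its most changed member, the median was 0.025, inside the random range.

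Of 26 proliferation genes, 5 rose in the authors' deposited table, all encoding subunits of the MCM helicase that unwinds DNA for replication, 0 fell, and 6 rose adjusted over the list alone. Mcm5 rose from 12.9 to 21.8 FPKM, Mcm2 from 9.13 to 14.7 FPKM, Mcm3 from 17.7 to 28.2 FPKM, Mcm4 from 8.67 to 12.8 FPKM and Mcm6 from 29.1 to 41.2 FPKM. The mitotic genes Mki67 and Ccnb1 stood at 2.47 and 2.67 FPKM and at 1.67 and 1.37 FPKM (q = 0.999 for both in the authors' deposited table). The list had a median of 0.10, at percentile 97.8. Without its most changed member the median was 0.081, inside the random range.

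Matrix remodelling genes went both ways, with 3 of 16 higher and 2 lower in the authors' deposited table, and 4 higher and 2 lower adjusted over the list alone. Spp1, which encodes osteopontin and shares its locus with Gm42793, rose from 2665 to 5093 FPKM, the collagenase gene Mmp13 from 37.4 to 83.3 FPKM and Adam8 from 351 to 588 FPKM. Mmp2, a gelatinase gene, fell from 7.02 to 3.68 FPKM and Mmp14 from 330 to 206 FPKM. The list's median was 0.01, at percentile 71.2. Of 19 tested genes of the ATF4 and unfolded protein response, Psat1, an enzyme of serine synthesis, rose from 12.3 to 19.0 FPKM, 0 fell, and the count was the same adjusted over the list alone. Their median was 0.10, just above the random range, and 0.085, inside it, without the most changed member. Of 17 immune checkpoint and suppressive ligand genes, Pilra, an inhibitory receptor, fell from 59.0 to 29.0 FPKM, 0 rose, and the median was -0.06, at percentile 24.0. Of 13 exosome-associated genes, the tetraspanin gene Cd82 fell from 38.6 to 17.3 FPKM, 0 rose, and the median was -0.07, at percentile 20.8. In both lists 1 fell adjusted over the list alone.

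**Figure D3:**
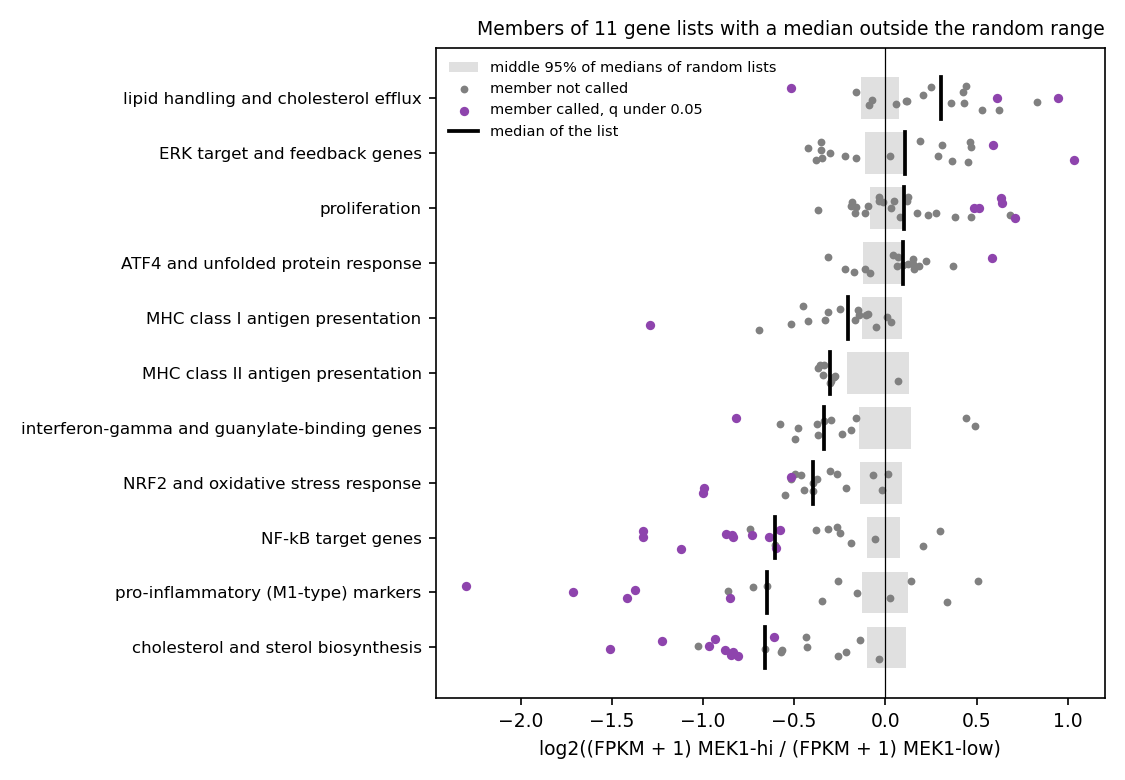
Log2 of the ratio of MEK1-hi to MEK1-low FPKM, each raised by 1 FPKM (x axis), for members of the 11 gene lists whose median lay outside the random range (y axis); points are loci, purple where called, black bars are medians and grey bands the middle 95% of medians of matched random lists. The medians run from -0.66 for sterol biosynthesis to 0.30 for lipid handling; those of the ERK target, proliferation and ATF4 lists lie at the edge of their bands.

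Cuffdiff called 0 of 24 glycolysis and hypoxia genes, 0 of 22 nuclear genes of oxidative phosphorylation, 0 of 20 lysosome and phagocytosis genes, 0 of 9 heat shock genes and 0 of 4 loci of mitochondrial genes. At an unadjusted p under 0.05, the higher and lower members were 1 and 1, 0 and 1, 3 and 2, 0 and 0, and 0 and 0. Adjusted over the list alone, 1 member of the lysosome and phagocytosis list, Itgax at 187 and 131 FPKM, was lower, and the other lists had 0. Their medians were -0.08, -0.03, -0.02, -0.05 and -0.16, all within the random range, and the lysosome mean was 0.04. Aldoa, a glycolytic enzyme, stood at 1362 and 1161 FPKM, and Pkm at 786 and 808 FPKM. Atp5b, of the ATP synthase, stood at 559 and 557 FPKM, Psap, which encodes prosaposin, at 5979 and 7263 FPKM, and Hsp90ab1 at 526 and 508 FPKM.

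None of the tested markers of other cell types was called by Cuffdiff. The highest T cell marker values were 0.308 FPKM with MEK1-low and 0.535 FPKM with MEK1-hi exosomes, and 0 of 14 were tested. Of 12 neutrophil markers, 3 were tested: Mmp8 stood at 179 and 184 FPKM, Csf3r at 37.8 and 30.8 FPKM and S100a8 at 35.5 and 22.6 FPKM, the last lower adjusted over the list alone. S100a9, Ly6g, Mpo and Elane were listed at 0 in both groups. The median of the 3 was -0.29, at percentile 3.62. Among fibroblast markers, Sparc stood at 16.9 and 13.4 FPKM and Acta2 at 3.94 and 4.34 FPKM, and the median was -0.14, at percentile 6.62. Among dendritic cell markers, Batf3 stood at 37.8 and 32.9 FPKM and Fscn1 at 8.25 and 5.87 FPKM, and the median was -0.19, at percentile 7.49. The highest markers of NK cells, B cells, mast cells, endothelium and erythroid cells stood at 1.68, 2.25, 1.15, 1.49 and 1.25 FPKM with MEK1-low and at 1.43, 2.09, 1.54, 0.711 and 0.652 FPKM with MEK1-hi exosomes. At an unadjusted p under 0.05, 1 fibroblast marker and 1 neutrophil marker were lower, and 0 of the others differed.

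Of the 33 lists, 27 had at least 3 loci at 1 FPKM or more and were compared with random lists. The medians of 7 fell below and of 4 above the random range, where 1.35 of 27 would be expected to lie outside by chance for independent genes.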

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

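The tests in this part were chosen after the results were seen. Among loci that Cuffdiff had left untested, 11 stood at 5 FPKM or more with MEK1-hi exosomes and were listed at 0 with MEK1-low exosomes, values that carry no test. The opposite held for 9 loci, listed at 0 with MEK1-hi exosomes and at 5 FPKM or more with MEK1-low exosomes. The locus of the microRNA gene Mir703 was listed at 0 and 151 FPKM, and that of Mir3473e at 114 and 0 FPKM. There were 22 untested loci at that level in either group, and all 22 held an annotated gene under 150 nt.

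The pattern weighed is the rise of the joined loci of St7 and Jpx, the highest folds among called loci, which were left out of the rule for named genes and chosen here after their values were seen. The St7 locus (mm10, chromosome 6, 17692933 to 17943025) rose from 6.75 to 193 FPKM and the Jpx locus (chromosome X, 103493556 to 103623790) from 1.25 to 40.4 FPKM (q = 0.00349 for both in the authors' deposited table). Both hold short annotated RNAs, Gm27762 of 109 nt in the first and Gm27875 of 123 nt in the second, for which a few fragments may give a large FPKM. With these 2 loci left out, 3.48% of 287 tested joined loci with a gene under 150 nt, at 1 FPKM or more in either group and above 0 in both, reached an absolute log2 fold change of 1, against 1.65% of 544 others (Fisher's exact test, two-sided, p = 0.140), so a contribution of the short RNAs cannot be told apart from a change in St7 and Jpx transcripts without values per gene and per sample. No biological explanation was tested.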

How the results depend on the processing

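The alternatives with a minimum test statistic, without loci holding a gene under 150 nt, for single named genes and for the second lists were chosen after seeing the data. No paired analysis was possible because the table holds 1 value per group. For the same reason leaving out each sample and a count model were not run, and the depth that would limit low values is unknown. The count of higher loci ran from 29 to 125 and that of lower loci from 85 to 268. It moved by over 1.5 times at q under 0.01, with 59 higher (155 lower), and at an absolute log2 fold change of at least 1, with 29 higher and 85 lower, where fewer loci can pass by construction. Lower loci outnumbered higher ones under every alternative run. For single genes, a pseudocount or centring cannot change a call, and Map2k1 lay at -0.15 on each log2 scale. Of 122 other genes taken by the rule or added, 89 were called. An absolute test statistic of at least 2 ended 5 of these calls, those of Fam117a, Epas1, Aif1l, Cpeb1 and Timeless. Calls ended for 14 at q under 0.01, 15 at a minimum of 5 FPKM, 29 at an absolute log2 fold change of at least 1, 7 without joined loci and 3 without loci holding a gene under 150 nt, and for 0 with the adjustment recomputed over expressed loci.

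Of the 11 lists outside the random range, 8 stayed outside on the same side under all 7 alternatives each, of which centring moves the random lists alike and cannot change a side. The ERK target list moved inside over members of at least 5 FPKM (0.025), with the mean (0.092) and without its most changed member (0.025). The ATF4 list did so with a pseudocount of 0.1 FPKM (0.10), the mean (0.078) and without its most changed member (0.085), and the proliferation list with a pseudocount of 5 FPKM (0.046) and without its most changed member (0.081). Of the 16 lists inside, M2-type markers (0.18) and neutrophil markers (-0.29) moved outside over members of at least 5 FPKM, and chemokines with the mean (0.11). Leaving out members moved the ERK target, ATF4, proliferation and M2-type medians, whereas all 3 neutrophil markers passed the filter and only the random range moved. The cause of the other moves was not tested. The 4 second lists kept their side under all 7 alternatives.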

Other observations

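The 26 genes and joined loci added to those of the rule, among them all genes of the next 2 paragraphs, were chosen after their values were seen. The tests of neutrophil content and of the size of the mitotic rise were also chosen after the results were seen. The second lists of genes were written after the calls but before their medians were computed, and it was known that few or none of their members had been called.

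C3, the central complement component, fell from 83.0 to 30.1 FPKM, and the joined locus of C2 and Cfb from 101 to 30.5 FPKM. Cfp, which encodes the stabilising factor properdin, rose from 36.4 to 66.6 FPKM. Clec4n, which encodes the pattern-recognition receptor dectin-2, fell from 714 to 403 FPKM, and Tlr2 from 65.5 to 33.4 FPKM. Gpr84, a receptor for medium-chain fatty acids, fell from 39.8 to 12.3 FPKM, and Cybb, the catalytic subunit of the phagocyte NADPH oxidase, from 549 to 316 FPKM. The transcription factor genes Cebpb and Nfe2l2, the latter encoding NRF2, fell from 299 to 121 FPKM and from 172 to 118 FPKM, and the cytokine signalling inhibitor gene Socs3 from 14.9 to 5.66 FPKM. All 26 passed the threshold in the authors' deposited table, with q-values between 0.00349 and 0.0110.

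Gas6, a bridging ligand for the uptake of dying cells, rose from 17.999 to 37.5 FPKM, Selenop, a selenium carrier, from 100.1 to 185 FPKM, Siglec1, which encodes sialoadhesin, from 31.8 to 57.1 FPKM, and the endocytic adaptor gene Dab2 from 72.3 to 136 FPKM. Timeless and Cdca7l, genes of replication and the cell cycle, rose from 1.48 to 3.52 FPKM and from 2.82 to 6.67 FPKM, the call of the first ending at an absolute test statistic of at least 2. Lgals1, which encodes galectin 1, rose from 798 to 1201 FPKM. The locus of Slpi, a protease inhibitor, joined with a microRNA gene, fell from 24.2 to 7.80 FPKM. The H2-Q4 and H2-Q6 genes and the annotated pseudogenes H2-Q5 and H2-K2 fell, the first from 81.2 to 45.1 FPKM, but share near-identical sequence with H2-Q7 and with one another, so their separate levels are uncertain. Ass1, an enzyme of arginine synthesis, stood at 6.83 and 1.86 FPKM, and its pseudogene copy Gm5424 at 346 and 111 FPKM, where reads of one may have been assigned to the other; the log2(FPKM + 1) value of Gm5424 was -1.63.

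The fall of NF-kB target genes may be an effect on inflammatory signalling. Without an untreated group, a lowering by MEK1-hi exosomes cannot be told apart from a raising by MEK1-low exosomes. More neutrophils in the MEK1-low samples would bring abundant neutrophil transcripts, yet 3 of 12 neutrophil markers reached 1 FPKM there, and S100a9, Retnlg and Ngp were listed at 0. The 3 were Mmp8 at 179 and 184 FPKM, Csf3r at 37.8 and 30.8 FPKM and S100a8 at 35.5 and 22.6 FPKM, the last lower adjusted over the list alone, and their median of -0.29 lay below the random range over members of at least 5 FPKM. S100a9 was listed at 0 beside S100a8 at 35.5 FPKM with MEK1-low exosomes, and whether a listing at 0 means absent transcripts could not be checked. A count of markers in 1 group also does not compare the groups, so a smaller difference in neutrophil content stays open. The labels mark the MEK1-low exosomes as GFP. Whether the exosomes differed in this or other contents than MEK1 was not tested, and stays open.

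A candidate explanation for the fall of sterol genes is a lower activity of SREBP2. A second list of 10 sterol pathway and SREBP target genes, none of them in the first, had a median of -0.25, at percentile 0.09 of random lists, with 10 of 10 values lower and 0 called. Sterol loading of the recipient cells might lower SREBP2 activity and raise LXR targets, but 7 further LXR targets had a median of -0.025 and a mean of 0.18, with 3 values higher and 4 lower. Under the rule written before the medians were computed, a median below 0 went against sterol loading, and this median met that rule. It lies below 0 by less than the SD of random medians (0.0946), a bound set after the value was seen, and is therefore taken to decide neither way. The fixed lipid handling list, with a median of 0.30 above all random lists, holds further LXR targets with higher values. Abca1 stood at 60.0 and 80.9 FPKM, Abcg1 at 33.6 and 60.7 FPKM and Mylip at 25.3 and 34.5 FPKM. Their q-values were 0.189, 0.103 and 0.104 in the authors' deposited table. Nr1h3, which encodes LXR alpha, fell from 63.1 to 43.7 FPKM. Of the 18 values of this list, 14 were higher and 4 lower. The rule did not cover this list, so sterol loading stays open. Sterol levels in the cells were not measured here.

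The rise of the MCM genes may be part of a wider rise of DNA replication genes. A second list of 39 replication loci had a median of 0.21, above all random lists, with 33 values higher, 6 lower and 0 called. Further DNA synthesis genes of the fixed proliferation list varied and were not called. Pcna stood at 79.3 and 104 FPKM and Tk1 at 11.3 and 16.1 FPKM. Tyms stood at 6.62 and 6.78 FPKM and Rrm2 at 7.25 and 7.06 FPKM. For more cells in mitosis, a list of 25 mitotic loci had a median of 0.029, at percentile 60.5, with 14 values higher and 11 lower, and a median of 0.040 (SD 0.25 across loci) without a pseudocount. That lies below the smallest rise of a called MCM gene, 0.50, by more than the SD, which is a spread across loci. This bound was partly fixed by the call, since no called locus had an absolute log2 fold change under 0.48. It was also known, when the mitosis list was written, that few or none of its members had been called. The comparison therefore cannot decide on a mitotic rise as large as that of the called MCM genes. A mitotic rise as large as that of the second replication list was not tested and, like a smaller one, stays open. Shared variation of these genes between samples, unrelated to the exosomes, was not tested.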
